A study of Homo sapiens with 6 samples.

How the data were processed

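Total RNA of the A2058 melanoma lines Mock, TET2WT and TET2M, grown for 7 days in medium with 4.5 or 1 g/L glucose, was hybridised to 6 Affymetrix arrays, 1 for each combination of line and glucose, per the labels. The deposited values are log2 probe set values made by the authors with Affymetrix Expression Console, per the submitters' processing notes. Its version, the summary method and the background correction are not given in the sources used here. The log base was read from the values, which ran from about 1.56 to 13.78. The sorted columns of the 6 arrays differed by at most 0.12, so the arrays had been brought to nearly 1 distribution before deposit, and the values carry 2 decimals.

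The table held 54675 probe sets, of which 62 were controls. In the platform's annotation, 1 gene symbol was given for 41097 probe sets, several for 1801 and none for 11777. The symbols of 41043 of the 41097 were brought up to date by gene ID with a reference gene table of the human assembly GRCh38.p14, used for names and for the chromosome and order of genes, and 54 kept the annotation's symbol. Probe sets whose mean over the 6 arrays lay below the 40th percentile (2.64 on the log2 scale) were left out as close to background. Each gene was represented by its probe set with the highest mean, which left 14428 genes. Control probe sets and probe sets naming several genes or none were left out of the gene comparisons, since a value could not be given to 1 gene.

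The deposited values were used without further normalization. Models were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), tables were handled with the package data.table (1.17.8), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The additive model had a term for the line and a term for glucose over all 6 arrays, with 2 residual degrees of freedom and a prior of 3.97. It gave the glucose difference over the 3 lines and the differences between TET2WT and Mock, TET2M and Mock, and TET2WT and TET2M over the 2 concentrations. The line was a term because the arrays of a line come from the same cells. The labels carry no replicate numbers. A second model added a glucose term for TET2WT alone, which set its glucose response against the mean response of Mock and TET2M, with 1 residual degree of freedom and a prior of 1.72. All tests were two-sided, adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The differences within a line rested on 2 arrays and were given without a test. As a rule without a variance estimate, genes at least 1.5-fold apart in the same direction in every line or at both concentrations were counted and set beside the count with 1 sign turned.

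The lists and the rule for naming genes were chosen before the data were examined. So were the tests and the alternatives, except those stated to have been chosen after the results had been seen. For each of the 5 comparisons the text names the 10 genes higher and the 10 lower with the largest of the smallest differences over the separate pairs of arrays. For each line it names the 5 highest and 5 lowest, for each list described up to 4 members with the largest differences, and in every comparison TET1, TET2, TET3, TXNIP, ARRDC4 and GAPDH. Genes with placeholder, open reading frame, LINC or antisense names were passed over. The 39 lists held 885 genes with a gene ID, of which 733 were tested. They covered metabolism, stress and signalling responses, the cell cycle, melanocyte and neural crest genes, DNA methylation and TET machinery, and markers of keratinocytes, fibroblasts, endothelial and blood cells. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The median of a list within a line was set against 10000 random lists matched on size and mean level. Genes were also counted by chromosome, which was decided after the differences had been seen, and 14412 of the 14428 genes had a chromosome in the reference table.

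The models were tested on simulated data in which 200 of 14428 genes changed. The first version drew the genes' variances from the moderated estimates. A second version, which drew them from the prior, was chosen after the first had been seen, and both are given. With variances from the prior, 27.5% of genes changed 1.5-fold by glucose were recovered and 0% in the other comparisons. At 2-fold, 97% were recovered for glucose, 92.5% for TET2WT against Mock, 90% for TET2M against Mock and 88% for TET2WT against TET2M, with 13, 9, 12 and 13 false calls. For the TET2WT-specific response 0.5% were recovered at 2-fold, with 5 false calls, and 97% at 4-fold. With no change simulated, 0 genes were called in all 5 comparisons. With moderated variances, recovery at 1.5-fold was 98.5% for glucose, 83%, 86% and 88% for the line comparisons in the same order, and 10% for the TET2WT-specific response. At 2-fold it was 100% for the first 4 comparisons and 94.5% for the TET2WT-specific response, with 15, 30, 14, 18 and 68 false calls. With no change simulated, that version called 0, 0, 0, 3 and 8 genes.

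The alternatives were no filter, a filter at the 60th percentile, quantile normalization, centring on the median, cyclic loess, the mean of a gene's probe sets, every probe set tested, an intensity trend or robust moderation in eBayes, and a threshold of 0.1. Further alternatives left out the line or glucose term, kept only the arrays of the lines compared, left out each array or line in turn, pooled Mock and TET2M, set another line apart, raised the fold of the rule, and used camera's estimated correlation. An alternative for values on a linear scale was not run, since the values are log2. Comparisons of TET2WT and TET2M with Mock use the same Mock arrays, and 100 simulations of unchanged lines gave the overlap and covariance that shared arrays produce when no line differs.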

Results

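Gene expression was measured in A2058, an established human melanoma cell line, on 6 Affymetrix arrays. There were 3 lines: a Mock line, a line overexpressing the wild-type construct TET2WT, and a line overexpressing the construct that the labels name TET2M and, in another field, Mut. TET2 is an enzyme that oxidises methylated cytosine in DNA. Each line was grown for 7 days in medium with high (4.5 g/L) or normal (1 g/L) glucose, and each of the 6 combinations was measured on 1 array. The median probe set value lay between 2.96 and 3.03 on the log2 scale and the highest between 13.72 and 13.78. The arrays had been brought to nearly 1 distribution before deposit, so this shared range is no check of their quality. The number of arrays limits the precision of every value. Differences are log2 differences, ± is the standard error from limma, and a gene passed when limma's adjusted p was under 0.05. No line was measured more than once at either concentration, and the error came from how far a difference varied over the 3 lines or over the 2 concentrations. These p-values therefore measure only the spread between single arrays, which may be technical.

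TET2 was higher in both overexpressing lines than in Mock and higher in TET2WT than in TET2M. Its probe set with the highest mean read 9.54 at high and 9.68 at normal glucose in TET2WT. The same probe set read 7.57 and 7.37 in TET2M and 3.81 and 4.13 in Mock. The difference from Mock was 5.64 ± 0.14 in TET2WT (adjusted p = 7.31e-05, limma) and 3.50 ± 0.14 in TET2M (adjusted p = 0.00124, limma). TET2WT exceeded TET2M by 2.14 ± 0.14 (adjusted p = 0.00187, limma). Another TET2 probe set gave the same order of lines, from 6.64 and 6.87 in TET2WT to 2.10 and 2.64 in Mock. The remaining TET2 probe set read between 5.15 and 5.41 on all 6 arrays. TET3, another enzyme of the family, was lower in TET2WT than in Mock, with a difference of -1.04 ± 0.096 (adjusted p = 0.00580, limma) and lower than in TET2M, with one of -0.72 ± 0.096 (adjusted p = 0.0190, limma). With the mean of the TET3 probe sets these differences were -0.45 and -0.32 and did not pass. TET3 did not pass between TET2M and Mock (-0.32 ± 0.096). TET1 did not pass in any of these comparisons, at -0.44 ± 0.11 in TET2WT and -0.27 ± 0.11 in TET2M against Mock and -0.17 ± 0.11 between TET2WT and TET2M.

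**Figure D1:**
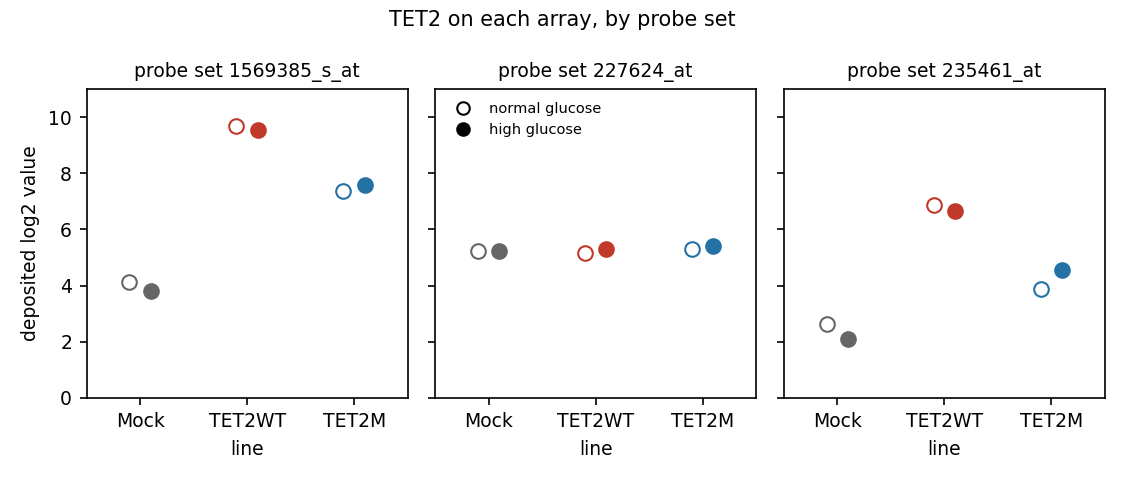
Deposited log2 value of each TET2 probe set (vertical axis) in the 3 lines (horizontal axis), with filled circles for high and open circles for normal glucose, 1 array each. In 2 of the panels TET2WT lies above TET2M and TET2M above Mock, and in the other all 6 arrays lie between 5.15 and 5.41.

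The TET2WT arrays stood apart from the other 4. On the first principal component of the tested genes, which held 48.7% of the variance, the TET2WT arrays lay at -21.4 and -23.8 and the Mock and TET2M arrays between 7.87 and 15.2. The second component, with 20.1% of the variance, placed the high-glucose array above the normal-glucose array in each of the 3 lines. Between 22 and 27 genes differed at least 2-fold between the glucose concentrations of a line. At high glucose 207 genes differed at least 2-fold between TET2WT and Mock, 176 between TET2WT and TET2M, and 34 between TET2M and Mock. At normal glucose these counts were 225, 205 and 39.

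The comparison of high with normal glucose over the 3 lines asked which transcripts followed the glucose concentration in these melanoma cells. LCN2, which encodes a siderophore-binding lipocalin, was lower at high glucose, with a difference of -1.36 ± 0.074 (adjusted p = 0.0247, limma; lower in 3 of 3 lines) and was the 1 gene that passed. TXNIP, the glucose-induced thioredoxin-interacting protein, had a difference of 1.87 ± 0.20 and was higher in 3 of 3 lines, with an adjusted p of 0.0783 in limma. Genes of sterol and fatty acid metabolism had negative differences in 3 of 3 lines. These were INSIG1, which retains SREBP proteins in the endoplasmic reticulum, at -1.18 ± 0.096, the stearoyl-CoA desaturase gene SCD at -1.13 ± 0.080 and the cholesterol transport gene STARD4 at -0.98 ± 0.084. The chemokine genes CXCL8 (-1.09 ± 0.12) and CXCL2 (-0.97 ± 0.11), the immediate early transcription factor gene EGR1 (-1.19 ± 0.15) and the inhibin beta A gene INHBA (-0.70 ± 0.073) also had negative differences in 3 of 3 lines. OLMALINC (-0.88 ± 0.076) and SORCS1 (-0.75 ± 0.082) completed the 10 named genes with negative differences. On the positive side stood EFEMP1, an extracellular matrix glycoprotein gene, at 1.15 ± 0.11, the filaggrin gene FLG at 1.44 ± 0.28, the cytokine gene IL24 at 1.10 ± 0.13 and EVA1A at 0.99 ± 0.15. PSPH, which encodes the enzyme of the last step of serine synthesis, had a difference of 1.04 ± 0.14, the elongation factor gene ELL2 of 0.95 ± 0.11 and CFAP95 of 0.92 ± 0.12. With the mean of its probe sets ELL2 was at 0.53. The CDP-diacylglycerol synthase gene CDS1 (0.92 ± 0.10) and the aryl hydrocarbon receptor target CYP1A1 (0.77 ± 0.079) were the last of the named genes with positive differences. Of these 19 genes without a pass, the smallest adjusted p in limma was 0.0589 for SCD and the largest 0.153 for FLG. The naming rule picked genes whose 3 lines agreed in direction, so that agreement is no added evidence for them.

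**Figure D2:**
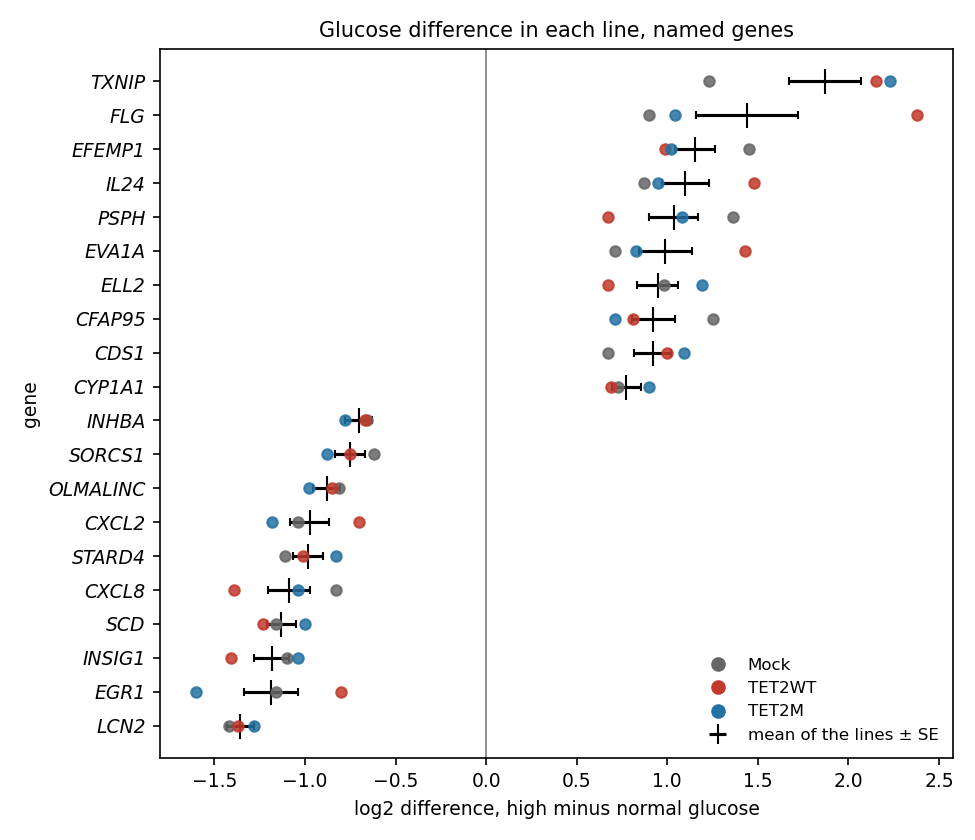
Log2 difference between high and normal glucose (horizontal axis) for the 20 named genes (vertical axis), with 1 point per line and a black bar with the mean of the 3 lines and its SE. All 3 lines lie on the same side of 0 for every gene shown, which the rule for naming genes required.

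ARRDC4, a relative of TXNIP in the arrestin family, had a difference of 0.72 ± 0.16 with the lowest of its 6 arrays below the low-value level of 2.64, and CFAP95 and SORCS1 also read below it on 1 array. GAPDH (-0.067 ± 0.070), TET1 (-0.12 ± 0.091), TET2 (-0.087 ± 0.11) and TET3 (0.24 ± 0.078) did not pass. At an adjusted p under 0.1, 54 genes were higher and 26 lower, and 2218 genes had an unadjusted p under 0.05 in limma. By a rule without a test, 31 genes differed at least 1.5-fold in the same direction in all 3 lines, 19 higher and 12 lower. With the sign turned in Mock, TET2WT or TET2M the same rule gave 0, 1 and 0 genes. The count of genes that passed was 573 with an intensity trend in the moderated variance, 0 without the line term, and 0 with any array or line left out, which lowers the residual degrees of freedom from 2 to 1. LCN2 kept its size throughout, with differences from -1.40 to -1.32 under 19 alternatives.

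Of the 39 gene lists, 12 passed for glucose in camera, limma's test of a list against all other genes, at a preset correlation of 0.01. With a correlation estimated for each list 0 of the 39 passed after adjustment, and 3 had an unadjusted p under 0.05. That version of camera had only 2 degrees of freedom, too few for a list to pass readily. It cannot decide whether correlation between genes accounts for the 12 passes. The ATF4 and amino acid response genes, which act in amino acid synthesis, transport and tRNA charging, had a median of 0.51 and were higher at high glucose in 25 of 26 members (adjusted p = 6.07e-21, camera; adjusted p = 0.358309 with an estimated correlation). Of the members of the 12 lists 0 passed over all genes tested. Of the ATF4 list 23 were higher when adjusted over the list alone, such as ALDH1L2 (1.05), PSPH, STC2 (0.72) and ATF3 (0.69). The mean over the 3 lines was higher at high glucose for all 35 measured G1/S and DNA replication genes, of which 29 were higher in Mock, 35 in TET2WT and 29 in TET2M, with a median of 0.18 (adjusted p = 7.11e-13, camera; adjusted p = 0.358309 with an estimated correlation). Of these 8 were higher when adjusted over the list alone, among them CCNE2 (0.68), CDC6 (0.48) and MCM5 (0.37). The G2/M genes had a median of 0.080 with 27 of 30 positive and 0 members past the adjustment over the list alone (adjusted p = 3.88e-05, camera; adjusted p = 0.388448 with an estimated correlation), with TTK at 0.32 and KIF23 at 0.30. The p53 targets had a median of 0.095 (adjusted p = 0.00221, camera; adjusted p = 0.358309 with an estimated correlation), and SESN2 (0.59) and FAS (0.43) were the 2 members higher when adjusted over the list alone. The 6 measured genes of the hexosamine pathway and O-GlcNAc turnover had a median of 0.15 (adjusted p = 0.0165, camera; adjusted p = 0.358309 with an estimated correlation). OGA (0.40), which removes O-GlcNAc, and UAP1 (0.28), which makes UDP-GlcNAc, were the 2 of them higher when adjusted over the list alone.

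The cholesterol biosynthesis genes were lower at high glucose in 17 of 18 members, with a median of -0.27 (adjusted p = 6.20e-08, camera; adjusted p = 0.358309 with an estimated correlation). Of these 8 were lower when adjusted over the list alone, with INSIG1, STARD4, DHCR7 (-0.59) and SREBF2 (-0.54) leading. The fatty acid synthesis genes had a median of -0.20 (adjusted p = 2.92e-04, camera; adjusted p = 0.358309 with an estimated correlation). Adjusted over the list alone, 5 of them were lower, among them SCD, SREBF1 (-0.66), ACACA (-0.45) and ACSS2 (-0.44), and 1 was higher, GPAM (0.41). The NF-kB and inflammatory genes had a median of -0.21, with 7 of 23 lower when adjusted over the list alone (adjusted p = 1.38e-05, camera; adjusted p = 0.358309 with an estimated correlation). CXCL8, CXCL2, CXCL1 (-0.61) and TNFAIP3 (-0.58) had the largest differences in that list. The immediate early genes had a median of -0.13 (adjusted p = 0.00230, camera; adjusted p = 0.358309 with an estimated correlation). Of these 8 were lower when adjusted over the list alone, among them EGR1, NR4A2 (-0.67) and SPRY4 (-0.61), and ATF3 was the 1 higher. Glycolysis genes had a median of -0.098 (adjusted p = 0.00576, camera; adjusted p = 0.358309 with an estimated correlation), with PFKFB4 (-0.46), a kinase of fructose 6-phosphate, the 1 member lower when adjusted over the list alone. Antigen presentation genes had a median of -0.098 (adjusted p = 0.0182, camera; adjusted p = 0.358309 with an estimated correlation), with NLRC5 at -0.32 and HLA-B at -0.25. Nuclear-encoded oxidative phosphorylation genes had a median of -0.077 (adjusted p = 0.0438, camera; adjusted p = 0.358309 with an estimated correlation), and 0 members of the antigen presentation and oxidative phosphorylation lists passed when adjusted over the list alone. The glucose-induced ChREBP and MondoA targets did not pass (adjusted p = 0.771, camera). Their median was -0.057 and their mean 0.10, with TXNIP, ARRDC4 (0.72) and ARRDC3 (-0.48) at the ends, while camera's direction was down. The ACTB control probe sets, whose 3′ minus 5′ difference rises as RNA is degraded, gave 2.06 at high and 1.90 at normal glucose in TET2WT, 2.02 and 1.94 in Mock, and 1.93 and 1.65 in TET2M. The same difference of the GAPDH control probe sets had no common direction, at 0.35 and 0.25 in TET2WT, 0.29 and 0.32 in Mock, and 0.28 at both concentrations in TET2M.

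Within each line the glucose difference rested on 2 arrays and was not tested. In Mock 22 genes differed at least 2-fold, 11 in each direction, with COL12A1 (1.59), EFEMP1 (1.45), JDP2 (1.43), ALDH1L2 (1.42) and PSPH (1.36) highest. LCN2 (-1.42), COXFA4L3 (-1.27), ANKRD1 (-1.22), MIR146A (-1.20) and EGR1 (-1.16) were lowest in Mock. In TET2WT 27 genes differed at least 2-fold, 10 higher and 17 lower, from FLG (2.38), TXNIP (2.15), DKK1 (2.05), GDA (1.58) and IL24 (1.48) to ITGA9 (-2.18), MGP (-1.84), LOXL4 (-1.58), INSIG1 (-1.41) and CXCL8 (-1.39). In TET2M 24 genes differed at least 2-fold, 17 higher and 7 lower, with TXNIP (2.23), LHX8 (1.75), SLC35G1 (1.5), PRR16 (1.34) and ALDH1L2 (1.25) highest. EGR1 (-1.60), LCN2 (-1.28), CXCL2 (-1.18), ITGA9 (-1.08) and INSIG1 (-1.04) were lowest in TET2M. The median of the ATF4 and amino acid response genes was 0.49 in Mock, 0.31 in TET2WT and 0.58 in TET2M, above all of 10000 random lists matched on size and mean level in each line. The median of the cholesterol biosynthesis genes was -0.30, -0.22 and -0.31 in the same order of lines, at the percentiles 0.00e+00, 0.0650 and 0.00e+00 of such lists. The random lists were drawn gene by gene and do not carry the correlation of genes that move together. Their percentiles are therefore no test of a glucose response.

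The comparison of TET2WT with Mock asked which transcripts differed with wild-type TET2 overexpression, as the mean over both glucose concentrations. The CXC chemokine genes CXCL1 (-4.26 ± 0.14), CXCL2 (-4.06 ± 0.13), CXCL8 (-3.96 ± 0.14) and CXCL3 (-3.59 ± 0.089) were lower in TET2WT, as was FDCSP (-6.61 ± 0.14), which like them lies on chromosome 4. The pentraxin gene PTX3 (-3.50 ± 0.099), LCN2 (-3.25 ± 0.090), the chemokine gene CCL2 (-2.93 ± 0.12), the teneurin gene TENM2 (-3.48 ± 0.089) and the transcription factor gene SOX11 (-3.34 ± 0.12) fell as well. Beside TET2 itself, the urotensin gene UTS2 rose by 4.39 ± 0.21, HSD17B3, an enzyme of testosterone synthesis, by 3.93 ± 0.16, CFAP251 by 3.53 ± 0.15 and the semaphorin gene SEMA3G by 3.52 ± 0.13. PPP1R1C (2.99 ± 0.17), the nicotinic receptor subunit gene CHRNA9 (2.63 ± 0.094), the extracellular glutathione peroxidase gene GPX3 (2.32 ± 0.099), the metalloproteinase inhibitor gene TIMP4 (2.30 ± 0.15) and the mannose-binding lectin gene MBL2 (2.09 ± 0.16) were also higher in TET2WT. All 20 named genes passed in limma, with adjusted p from 7.31e-05 for TET2 to 0.00295 for MBL2, and all lay on the same side at both concentrations, which the naming rule required. UTS2, CHRNA9, TIMP4 and MBL2 in Mock and FDCSP and TENM2 in TET2WT read below the low-value level of 2.64 on at least 1 array. TXNIP (0.55 ± 0.24), ARRDC4 (0.11 ± 0.20) and GAPDH (0.075 ± 0.086) did not pass.

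In all 608 genes passed between TET2WT and Mock, 290 higher and 318 lower, of which 170 differed at least 2-fold, and 2917 had an unadjusted p under 0.05 in limma. Genes on chromosome 13 made up 56 of the 318 lower genes and 3 of the 290 higher. The 257 tested genes of chromosome 13 had a median difference of -0.32, whereas the medians of the other 21 autosomes lay between -0.055 and 0.025. This chromosome was looked at after the lower genes had been seen. At least 1.5-fold in the same direction at both concentrations were 406 genes, 195 higher and 211 lower, against 6 with the sign turned at either concentration. The larger share turned with the scaling: quantile normalization gave 372 higher and 298 lower, and cyclic loess 387 and 306. The count of 608 was 1528 with an intensity trend in the moderated variance and 318 without the glucose term. With 1 residual degree of freedom in place of 2, 16 genes passed with the TET2M arrays left out, 5 higher and 11 lower, and 0 with an array of TET2WT or Mock left out.

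In all 6 gene lists passed between TET2WT and Mock in camera, and 0 after adjustment with an estimated correlation, where 2 had an unadjusted p under 0.05. The interferon response genes were higher in TET2WT with a median of 0.45 (adjusted p = 5.65e-08, camera; adjusted p = 0.600549 with an estimated correlation). Of 33 measured, 12 passed higher and 0 lower, and 18 were higher when adjusted over the list alone, such as IFITM1 (1.73), PARP9 (0.93), USP18 (0.85) and ISG20 (0.81). The NF-kB and inflammatory genes had a median of -0.62 (adjusted p = 1.46e-06, camera; adjusted p = 0.600549 with an estimated correlation). Of 23 measured, 10 passed lower, 2 higher and 11 did not pass, and 13 were lower and 4 higher when adjusted over the list alone. Besides the chemokine genes, PTGS2 (-1.97) and TNFAIP3 (-1.94) were lower, and the cytokine genes IL1B (1.06) and IL11 (0.76) were the 2 higher. The hypoxia response genes had a median of 0.31, with 5 of 21 passing higher, and 12 higher and 1 lower when adjusted over the list alone (adjusted p = 3.39e-05, camera; adjusted p = 0.720538 with an estimated correlation). ANGPTL4 (1.55), NDRG1 (1.06), BNIP3L (0.71) and ANKRD37 (0.70) were among the 5. Antigen presentation genes had a median of 0.14 (adjusted p = 0.00133, camera; adjusted p = 0.68051 with an estimated correlation), with the immunoproteasome gene PSMB9 (0.57) passing and 5 higher when adjusted over the list alone. Glycolysis genes had a median of 0.075 (adjusted p = 0.0204, camera; adjusted p = 0.720538 with an estimated correlation), with ALDOC (0.85) and ENO2 (0.77) passing and 4 higher when adjusted over the list alone. G1/S and DNA replication genes were lower with a median of -0.14 (adjusted p = 0.00844, camera; adjusted p = 0.80809 with an estimated correlation). The replication factor genes RFC3 (-0.74), the 1 member on chromosome 13, and RFC5 (-0.49) passed, and 3 were lower when adjusted over the list alone.

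**Figure D3:**
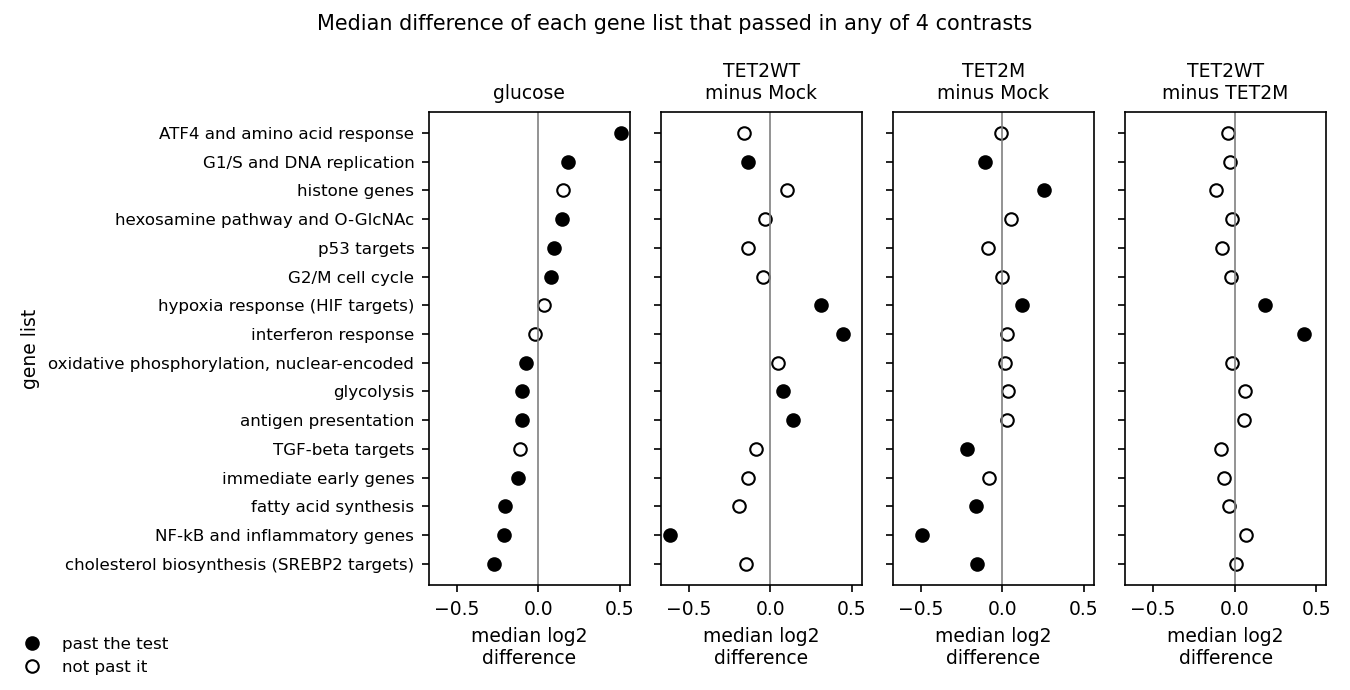
Median log2 difference (horizontal axis) of each gene list that passed in any of 4 contrasts (vertical axis), 1 panel per contrast, with filled circles for lists past camera's adjusted p of 0.05 and open circles for the others. The interferon response and NF-kB medians lie at 0.45 and -0.62 for TET2WT minus Mock.

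Other lists did not pass between TET2WT and Mock but held genes that did. Of 28 extracellular matrix and EMT genes 3 passed higher and 7 lower (adjusted p = 0.770, camera), with the collagen VI genes COL6A3 (1.52) and COL6A1 (1.21) higher and the metalloproteinase genes MMP9 (-2.41) and MMP1 (-1.11) lower. Adjusted over the list alone, 6 of them were higher and 8 lower. Of 23 NRF2 genes 4 passed lower: the aldo-keto reductase genes AKR1C2 (-1.13), AKR1C3 (-1.09) and AKR1C1 (-0.73) and the transporter gene ABCC2 (-0.57). That list had a median of 0.030 and a mean of -0.12 (adjusted p = 0.689, camera, direction down), with 2 higher and 5 lower when adjusted over the list alone. Among 14 cancer-testis genes MAGEB2 (1.46) passed higher and SSX1 (-2.16), PAGE1 (-1.49) and SPANXB1 (-0.83) lower (adjusted p = 0.770, camera). Among 15 TGF-beta targets SMAD6 (-1.18), ID3 (-1.13) and INHBA (-0.88) passed lower and ANGPTL4 higher (adjusted p = 0.244, camera). MITF (-0.60), the melanocyte transcription factor gene, passed lower and RAB27A (0.55) higher among 14 melanocyte genes (adjusted p = 0.499, camera). Of 18 genes of DNA methylation and TET machinery TET2 and DNMT3A (0.49) passed higher and TET3 lower, with a median of -0.013, a mean of 0.24 and an adjusted p of 0.835 in camera, direction up. TET2 is the overexpressed gene, and its difference of 5.64 raised that mean. The list was not tested without it, so its mean and direction are no evidence on the other members. Among 19 tumour suppressors often silenced by methylation CDKN1C (1.09) passed higher and SOCS3 (-0.80) lower (adjusted p = 0.689, camera).

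Marker lists of other cell types did not pass between TET2WT and Mock. KRT14 (-2.40) was the 1 of 15 keratinocyte and epithelial genes that passed, lower, and that list had a median of 0.010 and a mean of -0.18 (adjusted p = 0.516, camera, direction down). Of 12 fibroblast genes COL6A3, FBLN1 (1.02) and S100A4 (0.83) passed higher and LUM (-1.06) lower (adjusted p = 0.234, camera). ROBO4 (-0.99) and FLT1 (-0.86), the latter on chromosome 13, passed lower among 9 endothelial genes (adjusted p = 0.482, camera). Among 9 blood and immune genes LAPTM5 (2.19) passed higher and LYZ (-0.77) lower, with a median of -0.045, a mean of 0.15 and an adjusted p of 0.835 in camera, direction up.

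The comparison of TET2M with Mock asked the same of the TET2M construct. The chemokine genes CXCL3 (-2.36 ± 0.089), CXCL2 (-2.20 ± 0.13), CXCL1 (-2.10 ± 0.14), CXCL8 (-2.05 ± 0.14) and CCL2 (-1.78 ± 0.12) fell, as did FDCSP (-2.90 ± 0.14), LCN2 (-2.66 ± 0.090), PTX3 (-1.55 ± 0.099) and TNFAIP3 (-1.52 ± 0.14), an inhibitor of NF-kB signalling. Beside TET2, the GATA cofactor gene ZFPM2 rose by 1.84 ± 0.10, the cancer/testis gene CT55 by 1.36 ± 0.096 and MOK by 1.21 ± 0.086. These genes had adjusted p from 0.00124 for LCN2 to 0.0369 for TNFAIP3 in limma. PTGS2, the inducible cyclooxygenase gene, did not pass (-2.04 ± 0.23, adjusted p = 0.0697, limma). SGCZ (2.01 ± 0.34), PCDH17 (0.95 ± 0.10), STAC (0.94 ± 0.097), KCTD12 (0.92 ± 0.15), FBXL7 (0.89 ± 0.15) and MAGEB2 (0.86 ± 0.11) were higher at both concentrations without passing. SGCZ read below the low-value level of 2.64 in Mock at normal glucose, and its difference was 1.28 at high and 2.74 at normal glucose. TXNIP (0.42 ± 0.24), ARRDC4 (-0.38 ± 0.20) and GAPDH (0.0050 ± 0.086) did not pass either. In all 14 genes passed, 4 higher and 10 lower, and 1372 had an unadjusted p under 0.05. The tenth lower gene was LINC01419 (-2.03 ± 0.086), a noncoding RNA gene outside the naming rule and named after its values were seen. At least 1.5-fold at both concentrations were 74 genes, 20 higher and 54 lower, against 1 with the sign turned at either concentration. The count of 14 was 0 with any array left out, at 1 residual degree of freedom, and 149 with an intensity trend in the moderated variance.

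The NF-kB and inflammatory genes were lower in TET2M than in Mock in 22 of 23 members, with a median of -0.50 (adjusted p = 2.10e-20, camera; adjusted p = 0.385226 with an estimated correlation). Of these 6 passed lower and 14 were lower when adjusted over the list alone. In all 7 lists passed in camera, 2 up and 5 down, and 0 after adjustment with an estimated correlation, where the NF-kB list was the 1 with an unadjusted p under 0.05. The TGF-beta targets had a median of -0.22, with 0 of 15 passing and 3 lower when adjusted over the list alone (adjusted p = 0.00578, camera; adjusted p = 0.648355 with an estimated correlation). INHBA (-0.79) and ID1 (-0.62), which lies on chromosome 20, had large differences in that list. The G1/S and DNA replication genes had a median of -0.11 (adjusted p = 0.00578, camera; adjusted p = 0.663665 with an estimated correlation), and the members with the largest differences, PCNA (-0.40) and GINS1 (-0.29), lie on chromosome 20. The cholesterol biosynthesis genes had a median of -0.16, with STARD4 (-0.60) the 1 member lower when adjusted over the list alone (adjusted p = 0.0218, camera; adjusted p = 0.648355 with an estimated correlation). The fatty acid synthesis genes had a median of -0.16 (adjusted p = 0.0437, camera; adjusted p = 0.648355 with an estimated correlation), led by ACSS2 (-0.33), also on chromosome 20. The hypoxia response genes had a median of 0.12 (adjusted p = 0.00864, camera; adjusted p = 0.648355 with an estimated correlation), with ANGPTL4 at 0.53. The 5 measured histone genes had a median of 0.26 (adjusted p = 0.0317, camera; adjusted p = 0.648355 with an estimated correlation). In the G1/S, fatty acid synthesis, hypoxia and histone lists 0 members passed when adjusted over the list alone. The 441 tested genes of chromosome 20 had a median difference of -0.15 and the 458 of chromosome 14, where MOK lies, one of 0.080, whereas the medians of the other 20 autosomes lay between -0.040 and 0.010.

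**Figure D4:**
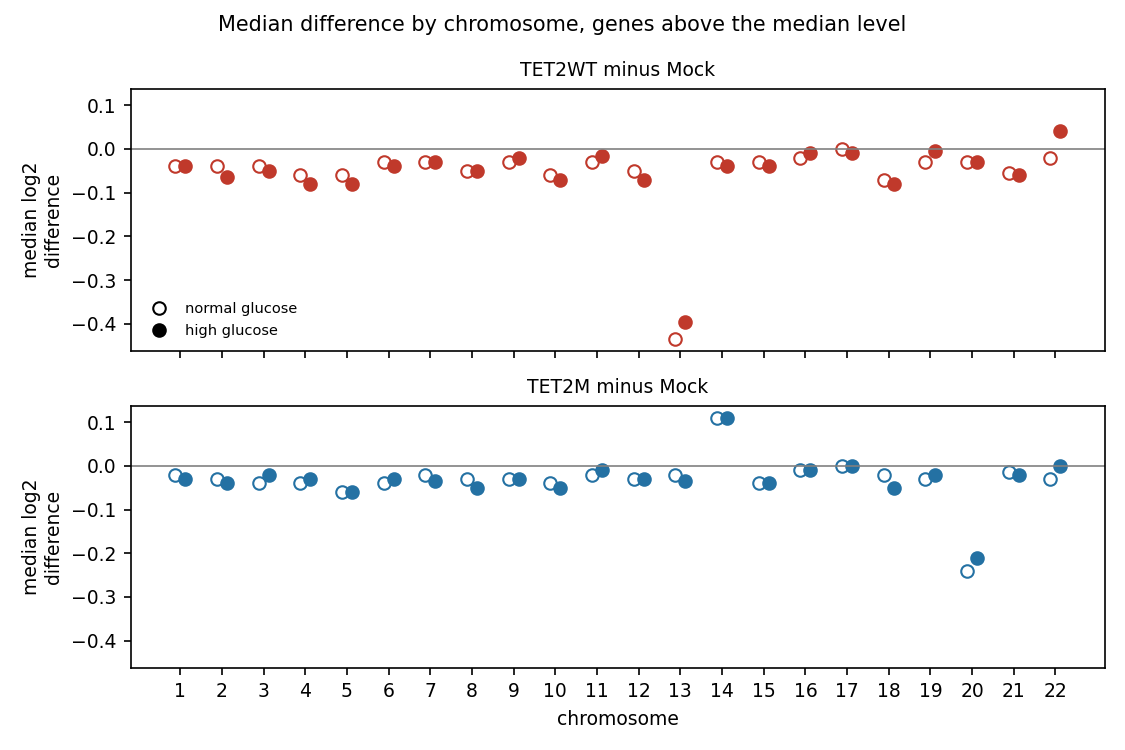
Median log2 difference from Mock (vertical axis) of the genes above the median level on each autosome (horizontal axis), for TET2WT in the upper and TET2M in the lower panel, with filled circles for high and open circles for normal glucose. Chromosome 13 lies apart in TET2WT, at -0.40 and -0.44, and chromosomes 20 and 14 lie apart in TET2M.

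The TET2WT and TET2M differences from Mock use the same Mock arrays. TET2, CT55 and MOK passed higher in both, 10 genes passed lower in both, among them FDCSP, LCN2, CXCL1, CXCL2, CXCL3, CXCL8, CCL2, PTX3 and TNFAIP3, and ZFPM2 passed in opposite directions (-2.25 in TET2WT and 1.84 in TET2M). Independent lists of these sizes would share 0.0804 higher and 0.220 lower genes, and 100 simulations of unchanged lines against the same Mock arrays shared 0.02 calls on average. The simulated lines carried no difference from Mock, so few shared calls could arise in them, and TET2 is the overexpressed gene itself. Across genes, which are not independent replicates, Pearson's r of the differences was 0.437 against 0.501 in the simulations, and their covariance was 0.0253 against 0.00679. There were too few Mock arrays to divide them with 2 in each part, so part of the excess may come from the shared arrays.

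**Figure D5:**
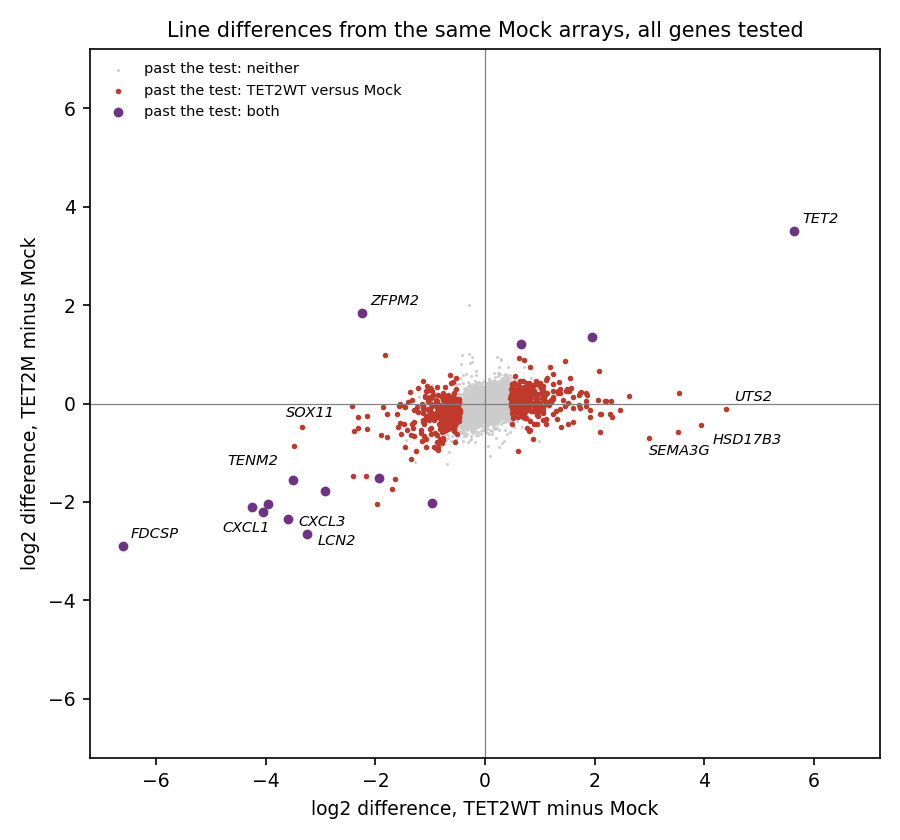
Log2 difference of TET2WT from Mock (horizontal axis) against that of TET2M from Mock (vertical axis) for each of the 14428 tested genes, coloured by which comparison the gene passed. The chemokine genes, LCN2 and FDCSP lie low in both, and ZFPM2 lies low in TET2WT and high in TET2M.

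The comparison of TET2WT with TET2M asked which transcripts differed between the constructs. UTS2 (4.51 ± 0.21), HSD17B3 (4.37 ± 0.16), SEMA3G (4.10 ± 0.13), PPP1R1C (3.68 ± 0.17), CFAP251 (3.32 ± 0.15), GPX3 (2.60 ± 0.099) and CHRNA9 (2.48 ± 0.094) were higher in TET2WT, as they were against Mock. The imprinted gene MEST (2.69 ± 0.18), the argininosuccinate synthase gene ASS1 (2.61 ± 0.26) and the sodium leak channel gene NALCN (2.49 ± 0.15) were higher too. ZFPM2 (-4.09 ± 0.10), FDCSP (-3.72 ± 0.14), SOX11 (-2.86 ± 0.12), the embryonic haemoglobin gene HBE1 (-2.82 ± 0.12) and TENM2 (-2.62 ± 0.089) were lower in TET2WT. The RNA-binding protein gene ELAVL2 (-2.39 ± 0.095), CXCL1 (-2.16 ± 0.14), the growth factor binding protein gene IGFBP3 (-2.04 ± 0.20), PTX3 (-1.95 ± 0.099) and the microfibril gene MFAP2 (-1.78 ± 0.087) were lower as well. All 20 passed, with adjusted p from 2.23e-04 for ZFPM2 to 0.00777 for ASS1 in limma. UTS2, CHRNA9, MEST, ASS1, ZFPM2, FDCSP, TENM2 and ELAVL2 read below the low-value level on at least 1 array. TXNIP (0.13 ± 0.24), ARRDC4 (0.48 ± 0.20) and GAPDH (0.070 ± 0.086) did not pass. In all 476 genes passed, 269 higher and 207 lower, of which 158 differed at least 2-fold, and 2546 had an unadjusted p under 0.05. These genes were not counted by chromosome. The shifts from Mock on chromosome 13 in TET2WT and on chromosomes 20 and 14 in TET2M may enter the count. At least 1.5-fold at both concentrations were 346 genes, 202 higher and 144 lower, against 0 with a sign turned. The count of 476 was 0 with any array left out, at 1 residual degree of freedom, and 1249 with an intensity trend in the moderated variance.

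The interferon response genes were higher in TET2WT than in TET2M with a median of 0.43 (adjusted p = 9.36e-08, camera; adjusted p = 0.80339 with an estimated correlation). Of 33 measured, 7 passed higher and 14 were higher when adjusted over the list alone, such as IFITM1 (1.51), CMPK2 (0.99), IFIH1 (0.71) and ISG15 (0.71). The hypoxia response genes had a median of 0.19 (adjusted p = 0.00371, camera; adjusted p = 0.967032 with an estimated correlation), with ANGPTL4 (1.03) and NDRG1 (0.69) passing higher and 9 higher and 1 lower when adjusted over the list alone. These were the 2 lists that passed at the preset correlation, and 0 passed after adjustment with an estimated correlation. The NF-kB and inflammatory genes did not (adjusted p = 0.738, camera, direction down), and their median of 0.070 and mean of -0.19 differed in sign. In that list IL11 (1.26), IL1B (1.25) and IL1A (0.87) passed higher and 5 genes passed lower. TET2WT against Mock and TET2WT against TET2M share the TET2WT arrays: 195 genes passed higher in both, 162 lower in both and 2, MOK and LINC01419, in opposite directions. Independent lists of these sizes would share 5.41 and 4.56 genes, and simulations of unchanged lines shared 0.03. Pearson's r across genes was 0.809 against 0.499 in the simulations, and the covariance 0.0716 against 0.00678. The simulated lines carried no difference, so few shared calls could arise in them. Any gene peculiar to the TET2WT line would pass in both comparisons. The overlap therefore cannot tell an effect of the construct from a property of that line or its arrays.

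The glucose response of TET2WT was compared with the mean response of Mock and TET2M to ask whether wild-type TET2 changes the response to glucose. The difference between the responses was 1.41 ± 0.12 for FLG, 1.25 ± 0.23 for the Wnt inhibitor gene DKK1 and 1.03 ± 0.12 for the matricellular protein gene CCN1, but neither these nor any other gene passed. FLG and DKK1 were higher at high glucose in all 3 lines, whereas CCN1 was higher in TET2WT (0.33) and lower in Mock (-0.76) and TET2M (-0.64). Also on the positive side stood RTEL1 (1.29 ± 0.32), ZNF606 (1.23 ± 0.18), CD209 (1.14 ± 0.17), SLC27A3 (1.10 ± 0.098), SLC22A6 (1.02 ± 0.11), HVCN1 (0.97 ± 0.098) and SLC35F1 (0.97 ± 0.10). The integrin gene ITGA9 (-1.34 ± 0.27), the matrix Gla protein gene MGP (-1.39 ± 0.47), the lysyl oxidase family gene LOXL4 (-0.98 ± 0.10) and the folate enzyme gene MTHFD2L (-1.17 ± 0.15) lay on the negative side. ZNF668 (-1.51 ± 0.098), MPND (-1.28 ± 0.14), SPAG16 (-1.16 ± 0.12), GSEC (-1.12 ± 0.20), TESC (-1.10 ± 0.099) and ZNF883 (-1.07 ± 0.11) did too. The lowest mean log2 levels among these named genes were those of SLC22A6 (3.22), CD209 (3.53), HVCN1 (3.65), ZNF668 (3.67) and MPND (3.78). On each array the median of the tested genes was 5.645 or more, so these genes lay toward the low end. With the mean of a gene's probe sets in place of the highest one, MTHFD2L was at -0.037, ITGA9 at -0.38, ZNF668 at -0.66, TESC at -0.50, CD209 at 0.45, RTEL1 at 0.69 and ZNF606 at 0.55. The values of TXNIP (0.42 ± 0.53), ARRDC4 (-0.73 ± 0.15), TET1 (-0.18 ± 0.18) and TET2 (-0.080 ± 0.29) did not pass, nor did TET3 (-0.015 ± 0.15) and GAPDH (0.025 ± 0.099), whose signs turned with the normalization. The smallest adjusted p over all genes was 0.531 in limma, shared by the 20 named genes, and 1325 genes had an unadjusted p under 0.05. This comparison had 1 residual degree of freedom, and on simulated data its recovery of genes changed 2-fold depended on the variances drawn, at 0.5% with variances from the prior and 94.5% with moderated variances.

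The ATF4 and amino acid response genes were lower in this comparison in 21 of 26 members, with a median of -0.16 (adjusted p = 0.00104, camera; adjusted p = 0.98127 with an estimated correlation). ALDH1L2 (-0.87) and ATF3 (-0.72) had the largest differences. The fatty acid oxidation genes were lower in 17 of 18 members, with a median of -0.18 (adjusted p = 0.00429, camera; adjusted p = 0.98127 with an estimated correlation), led by PDK4 (-0.85) and CPT2 (-0.43). With an estimated correlation, at 1 degree of freedom, 0 lists passed after adjustment. In both lists 0 members passed, over all genes or adjusted over the list alone. At least 1.5-fold in the same direction against both other lines were 277 genes, 128 higher and 149 lower. With arrays centred on the median 77 were higher and 232 lower, and a filter at the 60th percentile left 174 genes, 60 higher and 114 lower. The same rule gave 124 genes with Mock and 73 with TET2M as the line set apart.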

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

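The tests of the TET2 transcript level, of compressed TET2WT arrays and of a higher starting level at normal glucose, and the count over genes above the median level, were chosen after the results had been seen, and the bounds for the TET2 transcript level and for compressed TET2WT arrays were set anew after first ones had been applied.

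The TET2WT line stood apart from Mock in 608 genes. Second probe sets of the genes that passed moved in the gene's direction in 92.0% of 326 genes (300 genes, exact interval 88.5 to 94.7), against 64.98% of 6722 other genes, which argues against an artefact of single probe sets. Of 206 genes besides TET2 at least 2-fold apart at high glucose, the 179 with a log2 difference of at least 0.5 at normal glucose had a median ratio of the TET2M to the TET2WT difference there of 0.101 (0.0545 to 0.168). That interval ended below TET2's own ratios in the probe set read above background (0.584 on the log2 and 0.184 on the linear scale) and reached only the linear ratio of the other responding probe set, 0.0776 (0.296 on the log2 scale), whose Mock value lay at the low-value level, so the TET2 transcript level stays open, as the scale on which genes would follow it was not measured. A line or clone difference unrelated to TET2 cannot be told apart from an effect of the construct, since there was 1 line per construct, for genes on chromosome 13 a difference in copy number may account for lower values, and the difference between the TET2WT and TET2M proteins, which the design names, was not tested.

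The glucose response of the ATF4 and amino acid response genes was smaller in TET2WT than in the other lines, with a median difference of -0.16, and this difference between lines passed in camera, although not with an estimated correlation. Compressed TET2WT arrays would make every glucose difference smaller. The G1/S and DNA replication genes had a median TET2WT-specific difference of 0.115 (interval over genes 0.065 to 0.165, 35 genes), although that list did not pass in camera. Their glucose difference was thus not smaller on these arrays. Intervals over genes treat genes as independent and do not measure the spread between arrays or lines. With a list chosen after the results, the test cannot exclude compression of other genes. The median of the cholesterol and fatty acid synthesis genes, -0.04 (interval -0.15 to 0.12, 31 genes), was too wide to decide. A higher starting level at normal glucose is argued against by the list's median there, which lay -0.02 from the mean of the other lines (-0.095 to 0.093, 26 genes), while at high glucose it lay at -0.17 (-0.30 to 0.01). An effect of wild-type TET2 on this response may remain, and so may a property of the single TET2WT line or of its arrays.

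By the fold rule, more genes set the glucose response of TET2WT apart from both other lines (277) than set Mock (124) or TET2M (73) apart. Near background the TET2WT arrays were not noisier. On 21845 probe sets below the low-value level, the spread of the glucose difference in TET2WT was 0.967 of the mean of the other lines (0.955 to 0.980). Over the tested genes, which gave the 277, the SD of the glucose difference was 0.238 in TET2WT, 0.232 in Mock and 0.225 in TET2M. Noise at these levels stays open, since without replicate arrays it cannot be told from a wider response. Genes near the low end of the array are argued against as the whole of the pattern by genes above the median level, where 43 genes set TET2WT, 9 Mock and 8 TET2M apart, a ratio of 4.78. An effect of the construct, a property of the line and noise above background may each account for the pattern and were not separated by a test.

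The fatty acid oxidation genes had a median of -0.18 for the difference in glucose response between TET2WT and the other lines, and passed in camera at the preset correlation. With an estimated correlation, at 1 degree of freedom, they did not pass in camera (p = 0.281, adjusted p = 0.981), and 0 of 18 members passed. Among probe sets with no gene in the annotation, outside the genes compared, 20 of 4408 passed higher in TET2WT than in Mock and 27 lower. Among probe sets that name several genes, 6 of 1325 passed higher and 15 lower.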

How the results depend on the processing

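The count over genes above the median level was chosen after the results had been seen, and the other alternatives before. Of named genes under the alternatives, 1572 values kept direction and side of the threshold, 372 lost the pass, 48 gained it and 14 turned, none of which had passed. Most of these genes were named because their pairs of arrays agreed in direction, and the alternatives used the same arrays. Their stable direction was thus largely set by the naming rule. The 14 values that turned belonged to TET2, TET3, TXNIP, ARRDC4 and GAPDH, which were named whatever their values. Each list that passed was followed only under the alternative filters, normalizations and treatments of probe sets. There 194 values held and 8 did not, namely oxidative phosphorylation for glucose and the histone, cholesterol and fatty acid synthesis lists for TET2M against Mock. Lists were not refitted with an array, line or model term left out. Losses with an estimated correlation are not in that count. The numbers of genes that passed were not stable. For the glucose effect across the 3 lines the 1 gene became 2 with no filter, 5 with a filter at the 60th percentile, 3 with quantile normalization, 3 with cyclic loess, 5 with the mean of a gene's probe sets, 573 with an intensity trend (315 higher and 258 lower), 80 at a threshold of 0.1 and 0 without the line term, and leaving out 1 array or line gave 0 to 0. For TET2WT versus Mock the 608 became 1528 with an intensity trend (604 of them shared), 1115 at a threshold of 0.1, 318 without the glucose term, 16 with only the arrays of the lines compared, and 0 to 16 with 1 array left out. For TET2M versus Mock the 14 became 22 with a filter at the 60th percentile, 25 with the mean of probe sets, 149 with an intensity trend, 28 at a threshold of 0.1, 7 without the glucose term, 0 with only the arrays of the lines compared and 0 to 0 with 1 array left out. For TET2WT versus TET2M the 476 became 1249 with an intensity trend, 837 at a threshold of 0.1, 267 without the glucose term, 0 with only the arrays of the lines compared and 0 to 0 with 1 array left out. Leaving out an array or a line removes residual degrees of freedom, and the lone array of a line is then assumed to vary like the others; the cause of the other changes was not tested. The TET2WT-specific glucose response gave 0 genes under every alternative run, also with Mock and TET2M pooled or another line set apart, and had no version with an array left out. With an estimated correlation the lists that passed became 0 for glucose, 0 for TET2WT versus Mock, 0 for TET2M versus Mock, 0 for TET2WT versus TET2M and 0 for the TET2WT-specific glucose response. These versions had 2 degrees of freedom, or 1 for the TET2WT-specific response, too few for a pass to be likely. The 2 lists of the TET2WT-specific glucose response became 4 with no filter, 4 with a filter at the 60th percentile and 7 with every probe set tested, and the 6 lists of TET2WT versus Mock became 10 with every probe set tested. At 2-fold in place of 1.5-fold the rule counted 4 genes for glucose, 124 for TET2WT versus Mock, 21 for TET2M versus Mock, 121 for TET2WT versus TET2M and 13 for the TET2WT-specific glucose response. With every probe set tested it counted 56, 615, 524 and 593 probe sets for glucose, TET2WT versus Mock, TET2WT versus TET2M and the TET2WT-specific glucose response. The TET2WT-specific count of 277 was 174 with a filter at the 60th percentile and 43 over genes above the median level. The split of the 608 genes, 290 higher and 318 lower, turned to 372 and 298 with quantile normalization, 387 and 306 with cyclic loess and 162 and 156 without the glucose term. The split of the rule for TET2WT versus Mock turned from 195 and 211 to 226 and 182 with quantile normalization, 224 and 185 with cyclic loess and 63 and 61 at 2-fold. For the TET2WT-specific glucose response it turned from 128 and 149 to 158 and 152 with no filter and 98 and 92 with the mean of probe sets. Centring on the median changed the split of the rule from 19 higher and 12 lower to 25 and 9 for glucose, and from 128 and 149 to 77 and 232 for the TET2WT-specific glucose response. At least 2-fold within a line were 39 probe sets in Mock, 51 in TET2WT and 38 in TET2M with every probe set tested, and 13 genes in TET2M with the mean of probe sets. For the TET2WT-specific glucose response TET3 turned to 0.037 with quantile normalization, 0.014 with cyclic loess and 0.28 with the mean of probe sets, and GAPDH to -0.045 with median centring and -0.048 with cyclic loess. With the mean of probe sets TET2 against Mock was 3.34 in TET2WT and 1.83 in TET2M, TET3 was -0.45 in TET2WT against Mock and -0.32 between TET2WT and TET2M, ELL2 with glucose was 0.53, and in the TET2WT-specific glucose response MTHFD2L went from -1.17 to -0.037, ITGA9 from -1.34 to -0.38 and ZNF668 from -1.51 to -0.66. With arrays or lines left out, TET2 with glucose ran from -0.23 to 0.03, the latter without either Mock array or the Mock line. Against Mock, ARRDC4 in TET2WT ran from -0.26 (without the TET2WT array at normal glucose) to 0.47, with -0.16 without the Mock array at normal glucose. TXNIP in TET2M ran from -0.06 (without the Mock array at high glucose) to 0.90, and GAPDH in TET2M from -0.013 (without the TET2M array at normal glucose) to 0.023. TXNIP between TET2WT and TET2M ran from -0.14 (without the TET2M array at normal glucose) to 0.40, with -0.08 without the TET2WT array at high glucose. The cause of these turns was not tested. Signal near background limits genes below the low-value level of 2.64, where differences are compressed. No paired analysis by replicate was possible because each line was measured on 1 array per concentration, and the line served as the pair.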

Other observations

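Further gene lists did not pass between TET2WT and Mock, although some held members that did. The MYC and ribosome biogenesis genes were lower in TET2WT than in Mock in 16 of 20 members, with a median of -0.16 (adjusted p = 0.0877, camera), and 0 members passed. The p53 targets were lower in 16 of 18 members, with a median of -0.14 (adjusted p = 0.0907, camera). Of 15 neural crest genes TFAP2A (0.97) passed higher in TET2WT and the EMT transcription factor gene TWIST1 (-0.66) lower, with a median of 0.01 and a mean of -0.036 (adjusted p = 0.870, camera). Of 20 genes of the undifferentiated, AXL-high melanoma state LOXL2 (0.87) passed higher and INHBA (-0.88) lower (adjusted p = 0.642, camera). WIPI1 (1.45), an autophagy gene, was the 1 of 28 lysosome and autophagy genes that passed (adjusted p = 0.244, camera), and PDK4 (1.34), which inhibits pyruvate dehydrogenase, the 1 of 18 fatty acid oxidation genes (adjusted p = 0.320, camera).

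With glucose, the apoptosis regulators had a median of 0.05 (adjusted p = 0.0926, camera), and PMAIP1 (0.68) and FAS (0.43) were the 2 of 22 higher when adjusted over the list alone. The undifferentiated, AXL-high melanoma genes had a median of -0.09 and a mean of 0.0037 (adjusted p = 0.686, camera), with DKK1 (1.22), THBS1 (0.49) and FN1 (0.37) higher and INHBA (-0.70) lower when adjusted over the list alone. Of 15 neural crest genes 3 were higher and 3 lower when adjusted over the list alone, with TFAP2B (-0.63) and SNAI2 (-0.51) among the lower and ZEB2 (0.40) among the higher (adjusted p = 0.771, camera). The interferon response genes, higher in TET2WT, had a median of -0.02 and a mean of 0.0029 with glucose (adjusted p = 0.771, camera).

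The tests by chromosome were chosen after the results had been seen. Genes of chromosome 13 were lower in TET2WT than in Mock and genes of chromosome 20 lower in TET2M than in Mock, and a candidate explanation is fewer copies of these chromosomes in the cells of each line. The chromosome was picked as the one with the lowest median at high glucose, and its genes above the median level were counted at normal glucose. Both concentrations come from the same lines, so the count is no independent test. The intervals below treat genes on 1 pair of arrays as independent, and they do not measure the spread between cultures or lines. Of chromosome 13, 127 of 142 such genes, or 89.4%, were lower in TET2WT (exact interval 83.2 to 94.0), against 49.9% to 63.6% on the other autosomes. Of chromosome 20, 202 of 219, or 92.2%, were lower in TET2M (exact interval 87.9 to 95.4), against 22.9% to 64.1% on the others. The lower end of that range is chromosome 14, whose genes were mostly higher in TET2M. Genes in an order along the chromosome moved together: the first 4 blocks of 25 genes of chromosome 13 had medians from -0.42 to -0.59 at high glucose and the last block one of -0.24. On chromosome 14 the first 2 blocks lay at -0.03 and -0.07 in TET2M and the following 6 between 0.09 and 0.20. SUCLA2 (-1.02), a gene of the TCA cycle, and SPRY2 (-0.75), an immediate early gene, both on chromosome 13, were lower in TET2WT. With fewer copies in a line, such genes may differ between lines with no action of TET2 on them. The chemokine genes, LCN2 and the interferon response genes lie outside chromosomes 13 and 20, with 1 interferon response gene on chromosome 14. For these genes too, 1 line per construct cannot tell an effect of TET2 from a difference between lines. The median glucose difference on chromosome 13 was 0.0033. DNA copy number was not measured, and no other explanation of these blocks was tested.

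Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many genes as high against normal glucose, namely the real one with 1 gene, and the highest of the other splits gave 0. The real split is 1 of 4 that part the arrays of all 3 lines, and 10 splits are too few for a share under 0.05. A further hypothesis was that genes higher at high glucose would be lower in TET2WT than in Mock. Across the 14428 genes, which are not independent replicates, Pearson's r of the 2 differences was -0.095, just inside the bound set for no relation, whereas Spearman's rho of -0.16 lay beyond it.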
